A study of Mus musculus with 2 samples.

How the data were processed

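MicroRNA sequencing was done on the adrenal glands of newborn mice of the strain B6NCrl at postnatal day 0. Per the labels, each of the 2 libraries was made from both adrenals of 1 pup, and both pups came from the same pregnancy. The 2 libraries are biological replicates 1 and 2 of a single group and are called pup 1 and pup 2. The labels also give both samples the same donor identifier. The descriptions that name separate pups were followed, and if the identifier meant a single animal, the n of 2, the BCV and the pup differences would be technical. The sex of the pups was not collected. Per the labels, the libraries were restricted to RNA below 30 nucleotides, the size range of mature microRNAs (miRNAs), which are short RNAs cut from hairpin precursors that repress target transcripts.

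The authors deposited raw read counts per miRNA gene, with 1 table per library and no pooling or scaling. Per the sample notes among the deposited files, the reads were placed on the mouse assembly mm10 with the GENCODE M4 annotation. The aligner, its version and the adapter trimming are not given in the sources used here. The layout of each table, with 3 count columns (unstranded, same strand as the gene, opposite strand) after 4 rows that name no gene, is that of the gene counts of the aligner STAR. The row names show that reads mapping to several loci were kept apart from the gene rows. A mature miRNA encoded identically at several loci therefore gives gene counts that cover only part of its reads, and such genes are uncertain. Paralogues with nearly the same mature sequence, such as Mir23a and Mir23b or Mir10a and Mir10b, may also exchange reads.

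The same-strand column was used, because a rule set in advance took the stranded column with the larger sum. It held 1131762 counts in pup 1 and 3327743 in pup 2, which was 50.4% and 52.7% of all reads in the tables. Multi-mapped reads made up 34.9% and 32.2%, unmapped reads 10.6% and 11.2%, reads outside any gene 4.03% and 3.86%, and ambiguous reads 0 in both. These rows were left out of the library sizes. The opposite-strand column held 39345 and 104740 counts, and it was not used for the main results.

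Gene identifiers were matched to GENCODE M21, an annotation of the same assembly, for symbols, coordinates and host genes. Of 1973 gene rows, 1894 received a symbol, and the 79 others held 0 counts. Among the matched rows, 79 had another identifier version than the reference. RefSeq synonyms resolved older symbols in the gene lists. Coordinates are those of the annotated hairpin gene on mm10, counted from 1.

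The usual CPM scale, with a library sum of 1000000, was computed here from the deposited counts as each gene's count over the same-strand gene total. A gene was called detected at 10 CPM or more in both libraries. Log2 ratios of pup 2 over pup 1 were computed with a prior of 1 CPM among genes with a mean of at least 10 CPM, and a 2-fold difference was the threshold. Folds given without a log are plain ratios of CPM. With 1 library per pup, no p-value was computed, and each SD is over n = 2 pups. Shares of a single library have exact Clopper-Pearson 95% intervals, and folds have exact conditional 95% intervals for the ratio of 2 Poisson rates. Reads amplified by PCR without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only. The floor of 3 counts, a one-sided 95% limit for a count of 0 and so lower than the upper bound of the exact interval, was 2.65 CPM in pup 1 and 0.902 CPM in pup 2.

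The gene lists, the rule for named genes, the thresholds and most alternatives were chosen before the data were examined. The 19 lists were the let-7 and miR-98 family, the miR-17-92 cluster with its paralogues, the imprinted Dlk1-Dio3 locus, the imprinted H19 and Igf2 miRNAs, the imprinted Sfmbt2 intron cluster, and miRNAs known from neuronal and neuroendocrine, adrenocortical, erythroid, leukocyte, endothelial, stromal and smooth muscle, epithelial, kidney, liver, striated muscle, pluripotent and pancreatic cells, an X-linked testis-associated cluster, and genes whose mature sequence is encoded at more than one locus. Lists share some members. Genes were named by rule: the 20 with the highest mean CPM, the 3 most abundant members of each list, and the 5 with the largest log2 ratio in each direction. Any other gene named in the text was chosen after its values were seen.

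A list's level was placed among 10000 random lists of the same size drawn from genes with a count. Its median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 10 bins, if at least 3 members reached a mean of 10 CPM. These percentiles describe the 2 libraries only. They treat list members as separate draws, although members of a family or cluster can vary together. Adjacent miRNA genes on the same strand within 10 kb were compared with 10000 random pairings of the same genes. The biological coefficient of variation (BCV), the spread between pups beyond counting error, was the square root of edgeR's common dispersion in a design with 1 group. The alternatives were the unstranded column, DESeq2 size factors, edgeR's TMM scaling, minimums of 100 CPM or of 1 count, priors of 0.1 and 5 CPM, other totals, and leaving out each pup. Assigning opposite-strand counts to the overlapping RefSeq miRNA, and leaving out neighbour pairs of the Dlk1-Dio3 list, were added after the data were seen.

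The comparison of pups was tested on simulated data for the 284 genes with a mean of at least 10 CPM, 200 of which were changed, in a single simulated data set at a single dispersion. A simulated BCV of 0.25 was recovered as 0.246. Of genes changed 4-fold, 97% passed the 2-fold threshold, as did 47% of genes changed 2-fold and 11.9% of unchanged genes. A simulated list of 10 genes lowered 2-fold reached percentile 0, and 2 of 40 unchanged lists fell outside the central 95%. Genes were simulated as independent, so lists whose members vary together were not covered.

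Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.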

Results

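The miRNA content of the newborn mouse adrenal gland was measured in 2 littermates, each represented by 1 library from its pair of glands. The labels name separate pups but give both samples the same donor identifier, and the pups were taken as separate animals. The adrenal combines a steroid-producing cortex with a medulla of catecholamine-releasing chromaffin cells, so the glands hold endocrine, neuroendocrine, vascular and stromal cells together. The series holds no treatment or second tissue, and its design implies a description of miRNA levels and a comparison of the pups. The library of pup 1 held 1131762 same-strand miRNA gene counts and that of pup 2 held 3327743, a depth ratio of 2.94. Of 1973 miRNA genes, 635 had a count in at least 1 pup and 1338 had none in either. Both pups had 275 genes at 10 CPM or more, with 288 such genes in pup 1 and 289 in pup 2.

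A few miRNA genes held most of the counts in both glands. Mir126a, the endothelial miRNA encoded within an annotated exon of Egfl7, was the most abundant, with 9.20% ± 1.46 of all miRNA gene counts (SD, n = 2). Mir10a, of the Hoxb cluster, followed with 7.45% ± 0.208, then Mirlet7g with 5.72% ± 0.344, Mir23b with 5.49% ± 0.458 and Mirlet7i with 4.81% ± 0.296. Mir375, a miRNA known from pancreatic islets and other neuroendocrine cells, reached 3.40% ± 0.507 and ranked with Mir23a at 3.70% ± 0.0616, Mirlet7d at 3.67% ± 1.03, Mir99a at 3.45% ± 0.812 and Mir10b at 3.44% ± 0.110. These 10 genes took 50.3% ± 0.517 of the counts, and the 20 most abundant took 72.3% ± 0.141. The rest of the top 20 were Mir335, which lies in an intron of the imprinted gene Mest, then Mir22, Mir26b, Mir322, Mirlet7b, Mir99b, Mir143, Mir411, Mir21a and Mir127, with shares from 3.36% for Mir335 to 1.43% for Mir127. The place of Mirlet7b rests on pup 1, where it had 31174 CPM. In pup 2 it had 12391 CPM, below Mir30e at 13131 CPM and Mir139 at 12710 CPM, which are outside the top 20. Mean levels were at least 10000 CPM for 25 genes, at least 1000 CPM for 78 and at least 100 CPM for 188. Multi-mapped reads, 34.9% and 32.2% of all reads, were not counted, so these ranks and shares hold for the counted reads only.

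On mm10, Mir126a (ENSMUSG00000065540.1) lies at chr2:26591357-26591429 on the plus strand. Mir10a (ENSMUSG00000065519.1) lies outside any annotated host gene at chr11:96317165-96317274. Mirlet7g (ENSMUSG00000065440.1) lies in an intron of Wdr82 at chr9:106178840-106178927, and Mir23b (ENSMUSG00000065599.1) in an intron of 2010111I01Rik at chr13:63300484-63300557. Mirlet7i (ENSMUSG00000065406.2) lies in an exon of the pseudogene D630033A02Rik at chr10:122985640-122985724. Mir375 (ENSMUSG00000065616.2) has no annotated host at chr1:74900658-74900721, and Mir335 (ENSMUSG00000065501.1) lies at chr6:30741299-30741396.

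The let-7 and miR-98 family, which is known to accumulate as cells differentiate, was the list with the largest share, 18.0% ± 3.19 over 10 measured genes. Multi-mapped reads, such as those of let-7a, let-7c and let-7f, are not in this share. The miRNAs of the imprinted Dlk1-Dio3 locus, which are expressed from the maternal chromosome, together took 10.04% ± 0.536. Counts were found for 43 of the 47 measured genes of that locus, and 40 of them had a mean of 10 CPM or more. Its leading members were Mir411 with 16636 ± 4085 CPM, Mir127 with 14265 ± 284 CPM and Mir487b with 11750.0 ± 729 CPM. The medians of the let-7 list and of the Dlk1-Dio3 list were above those of all random lists of genes with a count, a percentile of 100 for each. List members without a count were left out of the medians. Other lists also ranked high, such as the adrenocortical list at 99.98 and multi-locus genes at 99.55. The lowest were striated muscle miRNAs at 31.68 and the testis-associated cluster at 9.56. The measured genes of the Dlk1-Dio3 list span chr12:109563692-109747960, with 46 on the plus strand. Mir127 (ENSMUSG00000070076.1, chr12:109592846-109592915) lies opposite an exon of Rtl1, and Mir411 (ENSMUSG00000065477.2) lies at chr12:109710175-109710256.

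**Figure D1:**
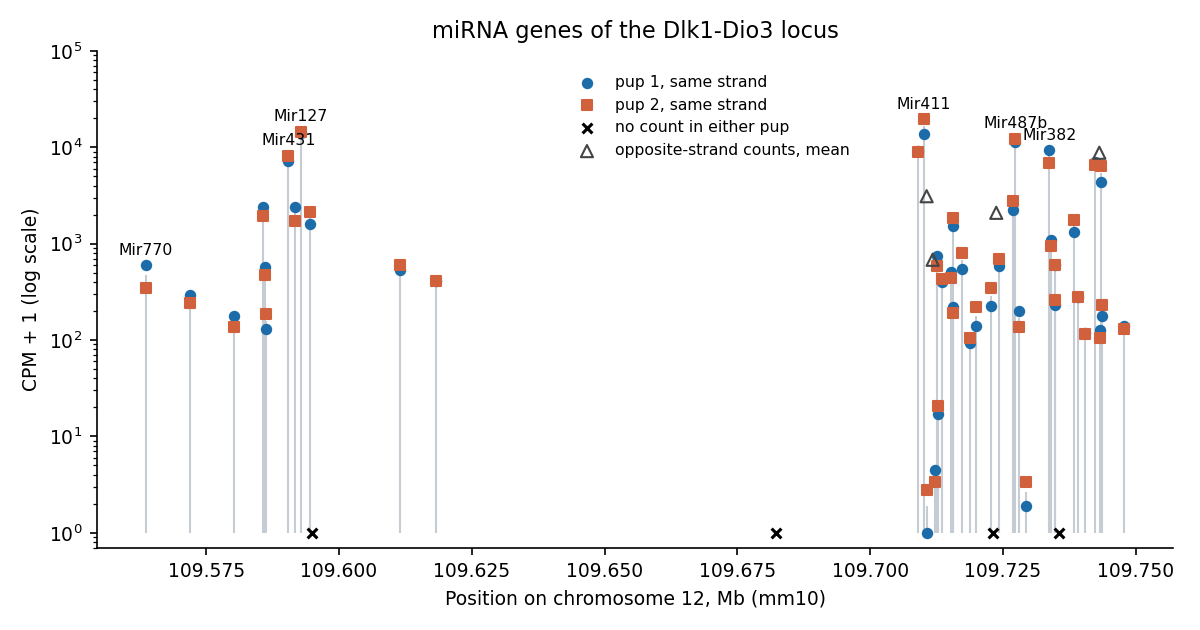
Levels of the miRNA genes of the Dlk1-Dio3 locus by position on chromosome 12 (mm10, Mb), as CPM + 1 on a log axis, with circles for pup 1, squares for pup 2, grey lines up to the mean, crosses for 4 genes with no count in either pup, and open triangles for mean opposite-strand counts. Mir411 and Mir127 are the highest of the listed genes, in the distal and the proximal block.

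The other imprinted miRNA groups had smaller shares of the counts. Mir483, in an intron of the growth factor gene Igf2 (chr7:142654924-142654996), made up 98.4% of the H19 and Igf2 list, whose share was 0.0732% ± 0.0110. Mir675, cut from the H19 transcript (chr7:142577064-142577147), had only 8 and 53 counts. In the cluster within an intron of Sfmbt2, 9 of 21 measured genes had a count, and the cluster took 0.217% ± 0.00203, led by Mir467d with 796 ± 8.36 CPM, Mir467e with 471 ± 3.12 CPM and Mir467c with 384 ± 33.2 CPM. Members such as Mir467a-1, Mir467b, Mir669a-1 and Mir297a-3 were at 0 counts in both pups, but the cluster holds closely similar copies and multi-mapped reads were not counted, so its share and its number of expressed genes are uncertain.

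A few genes gave most of the counts of the neuroendocrine and adrenocortical lists. The neuronal and neuroendocrine list took 8.55% ± 0.288 of counts, of which Mir375 alone gave 39.8%. It was followed by Mir335, the intronic miRNA of Mest, at 33601 ± 3393 CPM. Mir139, in an intron of Pde2a (chr7:101475376-101475443), had 13991 ± 1811 CPM. The share of this list rests mostly on Mir375 and Mir335, so it does not measure the amount of neuroendocrine cells. The brain miRNA genes Mir124a-1, Mir124a-2, Mir124a-3, Mir9-2 and Mir9-3 were not detected at this depth, and each had 0 counts in both pups, which allows up to 2.65 CPM in pup 1 and 0.902 CPM in pup 2 per gene by the 3-count floor. These are multi-locus genes whose multi-mapped reads were not counted. The list of miRNAs studied in adrenocortical steroid synthesis had all 21 measured genes at a mean of 10 CPM or more and took 4.02% ± 0.150. Its leading members were Mir21a with 14749 ± 1058 CPM in an exon of Vmp1 (chr11:86584067-86584158), Mir125a with 10889 ± 2282 CPM in an exon of Spaca6 (chr17:17830812-17830879), and Mir34c with 3681 ± 323 CPM (chr9:51103034-51103110). Mir21a alone gave 36.7% of the adrenocortical list, whose share does not measure the amount of cortex either.

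The lists of vascular and stromal miRNAs took another large share, carried by a few genes. The stromal and smooth muscle list took 13.0% ± 0.283, with 57.1% of it from Mir10a and further counts from Mir10b at 34446 ± 1096 CPM. The smooth muscle miRNA Mir143 had 16985 ± 3226 CPM (chr18:61649196-61649258), Mir214 had 3063 ± 119 CPM and Mir145a had 461 ± 68.8 CPM. The share rests mostly on Mir10a and Mir10b, so it does not measure the amount of stroma. The endothelial list took 9.22% ± 1.46, of which 99.7% was Mir126a, while Mir222 had 145 ± 10.1 CPM and Mir221 had 123 ± 19.8 CPM. The proliferation-associated miR-17-92 cluster with its paralogues took 0.922% ± 0.0749, with Mir17 at 3480.1 ± 223 CPM, Mir93 at 1449 ± 27.5 CPM and Mir106b at 1154 ± 201 CPM.

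Markers of neighbouring organs and blood ranged from sizeable to undetected. The kidney-enriched list took 2.16% ± 0.278, led by Mir30e with 11535 ± 2258 CPM, Mir30d with 5087 ± 30.6 CPM and Mir30a with 4461 ± 501 CPM, members of a family found in many tissues. Mir122, the abundant miRNA of hepatocytes (chr18:65248861-65248926), had 3529.98 ± 779 CPM, or 0.353% ± 0.0779. The leukocyte list took 0.335% ± 0.0360, with Mir342 at 2167 ± 277 CPM, the myeloid Mir223 at 794 ± 127 CPM and Mir146 at 239.7 ± 27.1 CPM. The erythroid list took 0.0338% ± 0.000151, with Mir451a at 262 ± 1.40 CPM, Mir486 at 47.2 ± 15.7 CPM and Mir144 at 29.4 ± 12.8 CPM. Epithelial miRNAs took 0.113% ± 0.0256, led by Mir203 with 688 ± 30.0 CPM, Mir429 with 197 ± 146 CPM and Mir200c with 108 ± 41.7 CPM.

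Pluripotent cell miRNAs took 0.0325% ± 0.00791, with Mir294 at 138 ± 50.6 CPM, Mir292 at 60.1 ± 22.5 CPM and Mir293 at 50.5 ± 3.49 CPM. The striated muscle list took 0.00875% in pup 1 and 0.0423% in pup 2 (0.0255% ± 0.0237), so its mean came mostly from pup 2. Mir206 gave 96.7% of it, while Mir208b had 2 and 12 counts and Mir1b had 3 and 8. The pancreas list had 1 and 7 counts in all, nearly all from Mir217, with 1 count of Mir216b and none of Mir216a. The X-linked testis-associated cluster had 4 and 8 counts over its 16 genes, among them Mir741, Mir471 and Mir871.

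**Figure D2:**
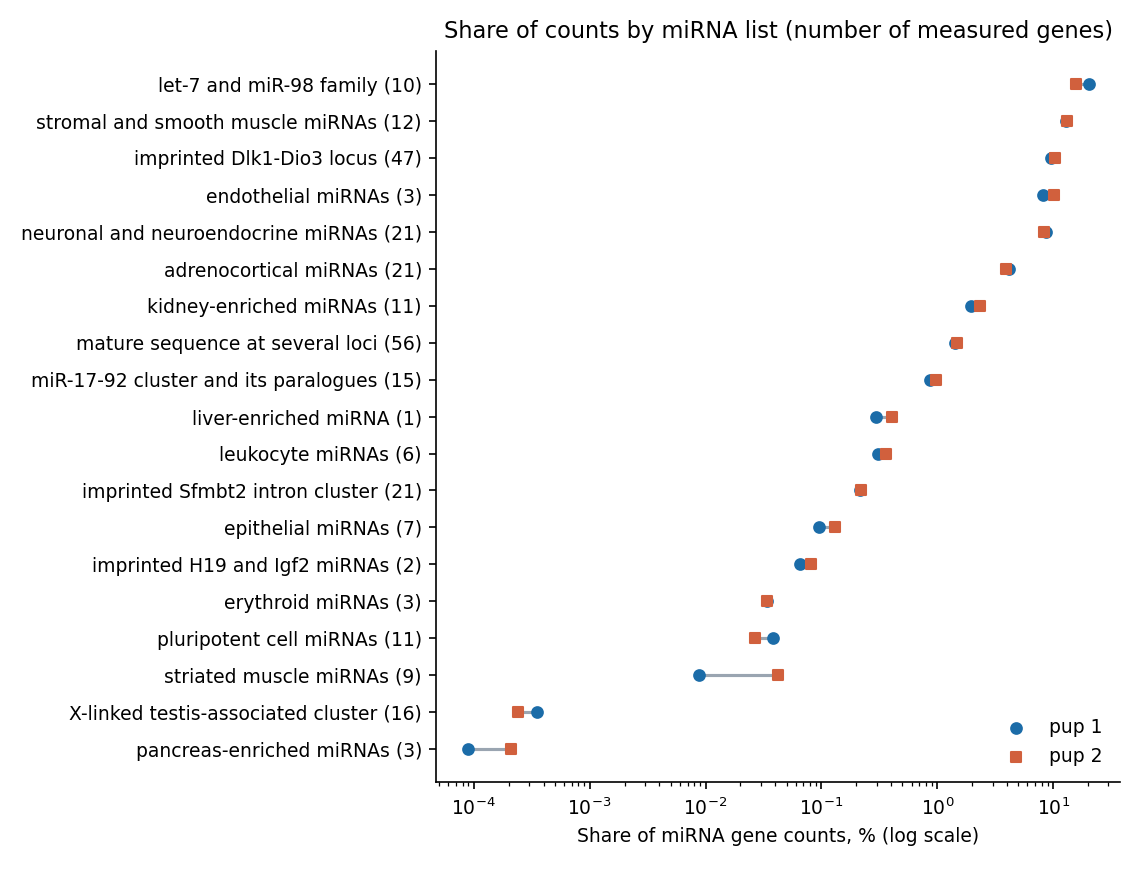
Share of miRNA gene counts taken by each gene list, in percent on a log axis, with a circle for pup 1 and a square for pup 2 joined by a line, and the number of measured genes in parentheses. The let-7 list is highest, at 20.2% in pup 1 and 15.7% in pup 2, and the testis and pancreas lists rest on 8 counts or fewer per pup.

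Genes whose mature sequence is encoded at more than one locus took 1.45% ± 0.0357 over 56 measured genes, led by Mirlet7f-2 with 4353 ± 12.2 CPM, Mir16-1 with 1808 ± 462 CPM and Mir92-1 with 1014 ± 17.2 CPM. Beside a single-locus neighbour of the same cluster, 16 of 17 such genes had the lower level, with a median log2 difference of -4.03. Pairs entered only if the single-locus gene had a mean of 10 CPM or more. No minimum was set for the multi-locus gene, so this choice of pairs favours the direction found. Mirlet7a-1 had 560.1 CPM beside 36747 CPM of Mirlet7d, and Mir30c-1 had 74.7 CPM beside 11535 CPM of Mir30e. Mir199a-2 had 26.4 CPM beside 3063 CPM of Mir214. This comparison was made after the values were seen, and the levels of multi-locus genes exclude multi-mapped reads. The list also holds Mir101a at 143 CPM and Mir101b at 704 CPM. By their names these are paralogues, like Mir23a and Mir23b, and not copies of a single mature sequence.

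The littermates were compared to see which miRNAs differed between glands of the same age and litter. Of 284 genes with a mean of 10 CPM or more, 269 (94.7%) lay within 2-fold, 10 were at least 2-fold higher in pup 2 and 5 at least 2-fold lower. In a single simulated set with no gene changed, at a BCV of 0.25, 18 of 284 genes passed 2-fold. The 15 observed genes are thus no more in number than that set gave. Its BCV lies near edgeR's 0.238, which came from these same libraries, and DESeq2's estimate of 0.128 was not simulated. Only the number of genes was compared, not the size of the largest differences. The largest difference was Mir1247, in an exon of Dio3os at the distal end of the Dlk1-Dio3 domain, which was 7.46-fold higher in pup 2 (95% counting interval 4.72 to 12.5, log2 ratio 2.83). Mir206, known from skeletal muscle, was 5.00-fold higher (4.05 to 6.24), and Mir196b, in an exon of Hoxa9, was 4.72-fold higher (4.14 to 5.41). The epithelial miRNAs Mir200b and Mir429, which lie in the same cluster, were 4.80-fold (3.35 to 7.11) and 3.20-fold (2.62 to 3.95) higher. In the other direction, Mirlet7b was lower in pup 2 by a log2 ratio of -1.33, from 31174 CPM in pup 1 to 12391 CPM in pup 2.

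The other genes at least 2-fold lower in pup 2 were Mir215, a kidney-enriched miRNA, with a log2 ratio of -1.57, Mir365-2 with -1.28, Mir1947 with -1.19 and Mir30c-1 with -1.11. Mir1947 rested on 24 and 29 counts and Mir365-2 on 38 and 44. The 10 higher genes were completed by Mir675 with a log2 ratio of 1.07 and, outside the naming rule, by Mir3105 with 1.58, Mir6240 with 1.18, Mir450-1 with 1.18 and Mir181a-2 at 2.17-fold (1.57 to 3.06). Mir30c-1, Mir365-2 and Mir181a-2 are on the list of multi-locus genes, so their counts leave out multi-mapped reads. That list may not hold every such gene, and others named here, such as Mir450-1, may be affected too. Mir200a, which lies between Mir429 and Mir200b, had 8 and 37 counts, and its ratio of 1.57 had an interval from 0.721 to 3.91. Mir133b, the neighbour of Mir206, had 0 and 4 counts. With a prior of 5 CPM, 11 genes passed 2-fold, and Mir450-1 at 0.95, Mir1947 at -0.93, Mir6240 at 0.86 and Mir675 at 0.79 on the log2 scale fell short.

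**Figure D3:**
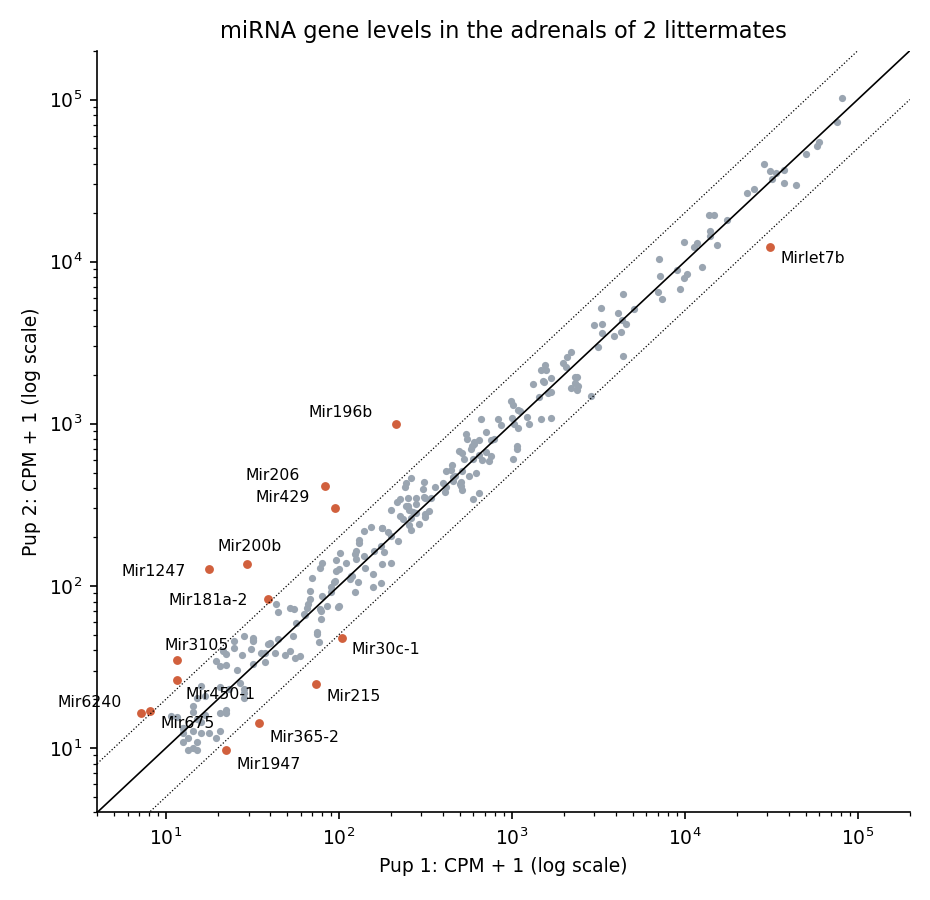
Levels of 284 miRNA genes in pup 1 (horizontal) and pup 2 (vertical), as CPM + 1 on log axes, with 1 point per gene, a solid line of equality and dotted lines at 2-fold. The 15 genes at least 2-fold apart are named, and Mirlet7b is the most abundant of them.

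Positions of these genes on mm10 are chr12:110278048-110278129 for Mir1247 (ENSMUSG00000080356.1), chr1:20679010-20679082 for Mir206 (ENSMUSG00000065559.1) and chr6:52230081-52230165 for Mir196b (ENSMUSG00000065443.1). Mir429 (ENSMUSG00000065427.1, chr4:156053905-156053987) and Mir200b (ENSMUSG00000065549.2, chr4:156055681-156055750) lie in an exon and an intron of the noncoding transcript Gm13648. Mirlet7b (ENSMUSG00000065564.1) lies in an exon of Lncppara at chr15:85707319-85707403, and Mir215 (ENSMUSG00000065562.1) in an exon of 2010103J01Rik at chr1:185313581-185313692.

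Taking gene lists instead of single genes, the let-7 family stood apart between the pups. Its share was 20.2% in pup 1 (95% interval 20.2 to 20.3) and 15.7% in pup 2 (15.7 to 15.8), and all 10 measured genes had a lower CPM in pup 2, although Mirlet7f-2 was higher with DESeq2 or TMM scaling, by 0.03 and 0.10 on the log2 scale. The ratio of pup 2 to pup 1 ran from 0.397 (0.392 to 0.403) for Mirlet7b, 0.573 (0.522 to 0.628) for Mirlet7c-1 and 0.670 (0.663 to 0.678) for Mirlet7d up to 0.918 (0.910 to 0.927) for Mirlet7g and 0.996 (0.964 to 1.03) for Mirlet7f-2. The median log2 ratio of the family was -0.36, at percentile 0.06 of matched random lists, whose central 95% ran from -0.20 to 0.27. All 10 genes have a stretch of 20 bases nearly identical to another miRNA gene, so they may exchange reads. Some share a host transcript, such as Mirlet7b and Mirlet7c-2 in Lncppara. The genes are thus not separate draws, and the percentile may overstate how far the family stands apart. Of the 10 genes, only Mirlet7b passed the 2-fold threshold. The genes of let-7a, let-7c and let-7f are multi-locus genes whose multi-mapped reads were not counted.

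**Figure D4:**
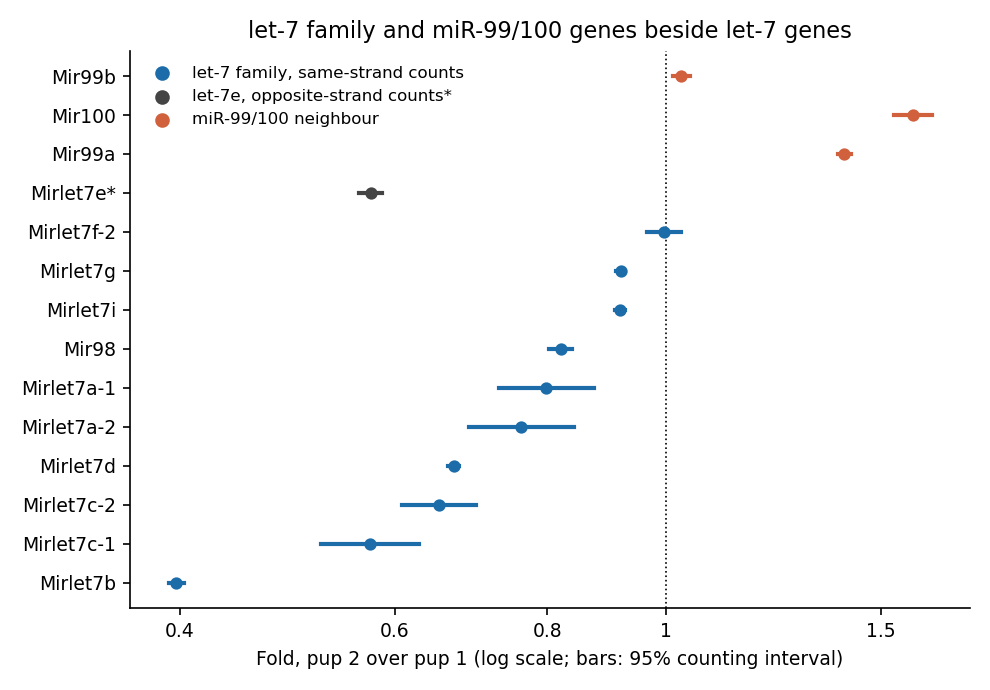
Ratio of CPM in pup 2 to pup 1 on a log axis for the 10 measured let-7 family genes, for let-7e read from opposite-strand counts, and for the miR-99/100 genes beside let-7 genes, with bars for 95% counting intervals and a dotted line at 1. Mirlet7b is lowest at 0.397, and Mir100 is highest at 1.59.

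The epithelial list was the other list outside the central 95% among the 14 lists with enough members. Its median log2 ratio was 0.87, at percentile 99.9, with 2 of 5 members at least 2-fold higher in pup 2, 4 of 5 higher and Mir203 at -0.09. Mir205 was 1.86-fold (1.23 to 2.92) and Mir200c 1.75-fold (1.39 to 2.22) higher. The stromal and smooth muscle list lay at percentile 94.95 with 8 of 10 genes higher, and the kidney-enriched list at 86.66 with 7 of 10 higher. The endothelial list lay at 76.5, miR-17-92 at 72.6, multi-locus genes at 55.1, neuronal and neuroendocrine miRNAs at 52.8 and leukocyte miRNAs at 46.0. Pluripotent cell miRNAs lay at 28.0, erythroid miRNAs at 27.8, the Sfmbt2 cluster at 25.8, the Dlk1-Dio3 locus at 25.8 and adrenocortical miRNAs at 21.0. In the Dlk1-Dio3 list, 22 of 40 genes were higher in pup 2 and 18 lower, and none passed 2-fold. That list ends before Mir1247, the gene of the same domain with the 7.46-fold difference. TMM scaling moved log2 ratios up by 0.11, which gave 26 higher and 14 lower in that list and placed all 5 epithelial and all 10 stromal genes higher in pup 2.

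Across the 284 genes, log2 levels of the littermates had a Pearson correlation of 0.986 and a Spearman correlation of 0.982, and genes are not independent replicates. The median log2 ratio was 0.08, with quartiles at -0.22 and 0.36. The BCV was 0.238 (bootstrap over genes 0.204 to 0.282) from edgeR's common dispersion and 0.128 from the median gene-wise dispersion of DESeq2, so the spread beyond counting depends on the estimator. Counting error alone gave a mean of 0.663 and at most 5 genes past 2-fold in 1000 draws, and a chi-square statistic of 160.3 per degree of freedom over 323 genes showed differences beyond counting noise, which library preparation alone can also give. With a simulated BCV of 0.25 and no gene changed, 18 genes passed 2-fold, so exceeding counting error does not single out changed genes.

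Clustered miRNA genes such as those of the Dlk1-Dio3 locus, which are transcribed together, were compared as neighbours. Over 98 adjacent pairs, the median absolute difference in log2 level was 2.34, against 2.84 in random pairings, and 652 of 10000 random pairings gave a median as small. Within 2 kb the difference was 2.23 over 76 pairs, and 311 of 10000 were as small, while among genes at 100 CPM or more it was 2.05 against 2.13 in random pairings, 3912 of which were as small. The pup-to-pup log2 ratios of neighbours differed by a median of 0.40, the same as in random pairings, 5164 of which were as small, and at 100 CPM or more by 0.32 against 0.37, with 1522 as small. Mir99a and Mirlet7c-1, 721 bases apart, had ratios of 1.40 (1.38 to 1.42) and 0.573.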

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

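The tests on opposite-strand counts, including the match to RefSeq, were chosen after the result was seen. The column of opposite-strand counts was not used in the comparisons, and 13 genes held 10 CPM or more in it in both pups, above the level that 3 counts set. Below 10 CPM, Mir126a also had more than 3 counts there in each pup, with 8 and 21. Gm25927, which lies across Mirlet7e (chr17:17830343-17830459), had 9652 ± 3702 CPM (SD, n = 2), and Gm24321, across Mir409 in the Dlk1-Dio3 locus, had 8755 ± 511 CPM. Gm24083, across Mir191, had 4099 ± 314 CPM, and Gm25301, across Mir378a, had 3393 ± 146 CPM. In the Dlk1-Dio3 locus, Mir299b, across Mir299a, had 3101 ± 226 CPM, Gm25252, across Mir376a, had 2086 ± 655 CPM, and Gm25750, across Mir380, had 679 ± 176 CPM. Mir142b, across the leukocyte miRNA gene Mir142, had 678 ± 253 CPM, Mir497b, across Mir497, had 283 ± 68.0 CPM, and Gm24111, across Mirlet7f-1, had 269 ± 48.3 CPM. Lower values were found for Mir337, across Mir3544, with 43.2 ± 8.85 CPM, for Mir3074-1, across Mir24-1, with 40.8 ± 5.21 CPM, and for Mir203, across Gm51289, with 17.5 ± 1.43 CPM.

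Strand errors or antisense reads spread over all loci are argued against, since the highest opposite-strand share among 29 abundant genes was 0.0105%, while the column as a whole held 3.36% and 3.05% of the counts of both strands. In each pup at least 99.9% of opposite-strand counts lay in genes crossed by a RefSeq miRNA that has no row of its own in the tables used here. A candidate explanation is therefore that these counts are reads of the overlapping miRNAs, such as let-7e and miR-409, counted against a gene annotated on the other strand. No biological explanation was tested. With these counts assigned to the overlapping miRNA, the Dlk1-Dio3 share was 11.1% ± 0.696 and the let-7 share 18.4% ± 3.41.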

How the results depend on the processing

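Assigning opposite-strand counts to RefSeq miRNAs and leaving out Dlk1-Dio3 pairs were tried after the data were seen, and every other alternative was planned. Of 804 alternative values for 180 results, 696 kept their direction and side of the threshold or stayed within the spread, and 0 results past a threshold changed sign. Leaving out a pup cannot move a list share or a gene level by more than the SD between the pups. Those values were therefore unchanged by construction. DESeq2 and TMM scaling moved all log2 ratios alike, by about 0.03 and 0.11, and a changed prior cannot change a ratio's sign. Neither could reverse a ratio past 2-fold, and a shift common to all genes can hardly move a list percentile. The 0 sign changes and the count of 696 therefore overstate how much was tested. Log2 ratios near 0 changed sign in 7 cases over 6 named genes, among them Mir10a (0.05), Mir23a (0.07) and Mirlet7f-2 (0.10) with TMM scaling. With multi-mapped and unassigned reads in the total, the 10 most abundant genes took 29.1%, let-7 10.4%, stromal miRNAs 7.56%, the Dlk1-Dio3 locus 5.82%, endothelial 5.35%, neuroendocrine 4.95%, adrenocortical 2.32%, kidney 1.25% and multi-locus genes 0.838%, because the total grew. Without Mir126a in the total, the shares were 14.4% for stromal miRNAs, 11.1% for the Dlk1-Dio3 locus, 9.42% for neuroendocrine, 4.42% for adrenocortical, 1.59% for multi-locus and 0.0295% for endothelial miRNAs. The unstranded column gave 48.7% for the 10 most abundant genes, 12.6% for stromal miRNAs and 1.40% for multi-locus genes. The added assignment gave 11.1% for the Dlk1-Dio3 locus. A minimum of 100 CPM left 178 detected genes, 4 genes past 2-fold and a Spearman correlation of 0.972, because fewer genes entered. With no minimum beyond 1 count, 85 genes passed 2-fold, 42 higher and 43 lower in pup 2, so 49.4% were higher against 66.7% in the main result, and the Spearman correlation was 0.918, as genes with few counts entered. The median gene-wise dispersion of DESeq2 gave a BCV of 0.128, and the cause was not tested. Neighbours within 2 kb differed in level by 2.23, with 311 of 10000 random pairings as small, and at 100 CPM by 2.05 with 3912 as small. Leaving out each pup in turn gave 50.8% to 51.0% for the 10 most abundant genes and 0.00875% to 0.0423% for striated muscle miRNAs, and it gave no value for pup differences, correlations or the BCV. A prior of 5 CPM left 11 of the 15 genes past 2-fold (7 higher, 4 lower), without Mir450-1, Mir1947, Mir6240 and Mir675. Of 276 levels of named genes, 64 moved by more than the spread between the pups, 51 of them with the larger total. The 276 include the levels without a pup, which could not move by this rule. No paired analysis was possible because the series holds a single group. The depth of pup 1 limits rare genes, since 3 counts there equal 2.65 CPM.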

Other observations

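The tests of GC content, near-identical copies, cluster partners, counting error and other tissues in this part were chosen after the results were seen, while the list percentiles were planned. On the X chromosome, Mir322 had 24717 ± 2595 CPM and its cluster neighbour Mir503 had 502 ± 76.8 CPM (SD, n = 2), with ratios of pup 2 to pup 1 of 1.16 (95% counting interval 1.14 to 1.18) and 1.24 (1.13 to 1.37). Among the adrenocortical list, Mir202 had 897 ± 238 CPM with a ratio of 0.684 (0.638 to 0.734), Mir214 had 3063 ± 119 CPM with 0.947 (0.911 to 0.984), and Mir132 had 513 ± 4.07 CPM with 0.989 (0.900 to 1.09). Of the miR-7 genes, Mir7b had 1925 ± 520.2 CPM, Mir7-1 had 373 ± 92.2 CPM and Mir7-2 had 289.6 ± 35.2 CPM. The miR-183 cluster held Mir183 at 295 ± 25.05 CPM, Mir182 at 277 ± 48.7 CPM and Mir96 at 62.3 ± 11.8 CPM. Apart from Mir322, these genes were chosen after their values were seen.

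The lower let-7 family in pup 2, at percentile 0.06, lay nearest to the edge of the random range among the 14 lists. As the let-7 genes are not separate draws, that percentile may overstate the difference. After a linear trend on hairpin GC content was removed, the let-7 median still lay at percentile 0.02. That correction moved no gene's log2 ratio by more than 0.13, too little to bring the let-7 median into the random range. The GC content of the mature sequence and trends that are not linear were not tested. The 102 other genes with a near-identical copy had a median log2 ratio of 0.19. It lay above the random range of 0.01 to 0.17, which argues against reads lost to copies. A lower output of the shared primary transcripts stays open: in 3 of 3 clusters the miR-99 or miR-100 gene had the higher ratio (Mir99a 1.40 beside 0.573 for Mirlet7c-1, Mir100 1.59 beside 0.761 for Mirlet7a-2, Mir99b 1.03 beside 0.573 for let-7e), but their counting intervals leave out library noise, and neighbouring genes in general were not clearly closer in ratio than random pairs (5164 of 10000 as small, and 1522 among genes at 100 CPM or more). The miR-125 genes of the same clusters lay between, at 0.979 for Mir125b-2, 0.809 for Mir125b-1 and 0.742 for Mir125a. A difference in let-7 processing or stability between the pups may be an explanation, as may differences in RNA handling or ligation between the libraries, and neither was tested.

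The 5 largest differences, Mir1247, Mir206, Mir196b, Mir200b and Mir429, could reflect a few cells of another tissue in the pup 2 sample. Counting error at the lower depth of pup 1 is argued against, since the smallest lower bound of the 5 intervals was 2.62. The 5 genes were picked as the largest ratios of the same counts, and the intervals are not adjusted for that choice. More kidney in the pup 2 sample stays open, since the kidney-enriched list lay at percentile 86.66, with Mir30e at 1.32-fold (1.29 to 1.35) and Mir192 at 1.57-fold (1.28 to 1.94) but Mir215 at 0.328-fold (0.237 to 0.452) and Mir30c-1 at 0.457-fold (0.357 to 0.587) going the other way, and members of the miR-30 family are expressed in many tissues. More skeletal muscle cannot be told apart either, because 0 of the striated muscle genes other than Mir206 reached 10 CPM, and the multi-mapped reads of Mir1a-1 and the Mir133a genes were not counted. Sex and other differences between the littermates stay open as untested explanations.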
